A study of Mus musculus with 18 samples.

How the data were processed

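RNA was sequenced from sorted nuclei of CA1 pyramidal and dentate gyrus granule neurons of mice raised in enriched, standard or impoverished housing, 3 libraries per neuron type and condition and 18 in all, each from nuclei of 3 mice per the labels. The deposited table holds counts per gene (unit: counts), read as such because all values are whole numbers. Per the labels' protocols the authors checked reads with FastQC, trimmed them with Trim Galore 0.39, aligned them to mm10 with STAR 2.7.9a and used SAMtools 1.13 and deepTools 3.5.1, and the labels name no read counter or annotation. Columns marked EI and NC were taken as impoverished and standard, which is in doubt. All 18 columns were matched to samples and none was left out.

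The table lists 55487 genes, of which 55141 had a symbol and 55227 mm10 coordinates. The 37 mitochondrial genes and 1562 genes of chromosome Y hold 0 counts in every library, and Rn45s is absent, so that a planned fit without mitochondrial genes and Rn45s removed nothing. Totals per library ran from 34181104 to 36537887 counts, with 27370 to 27979 genes detected, and gene-level biological variation (edgeR common dispersion) was 13.7% in CA1 and 11.9% in DG. Data were simulated at this depth with n = 3 per group and 50 genes changed at each fold. At 1.5-, 2- and 3-fold edgeR recovered 11, 35 and 45 in CA1 EE against IE and 15, 39 and 47 in DG. False calls numbered 8 and 14, by DESeq2 28 and 18, and by edgeR without a filter on low counts 50 and 32. With labels of the real libraries exchanged, edgeR called up to 2000 and 1046, so these numbers describe the simulation only. None of the 153 pairs of libraries was a copy (counts differed in at least 27877 genes).

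Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05). EE against IE, EE against SC and IE against SC were tested in each neuron type on its 9 libraries, and their differences between neuron types (DG effect minus CA1 effect) and CA1 against DG on all 18. Log2 fold changes are those of edgeR, log CPM values for list scores used a prior count of 2, and CPM values used the TMM library sizes. DESeq2 1.42.0 and limma 3.58.1 (limma-voom) were run beside edgeR. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

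A total of 38 gene lists was written before the data were examined, and 35 had the 3 tested members needed in the comparisons. They cover AP-1 subunits, rapid immediate early, delayed activity-regulated, MAPK feedback, glucocorticoid-responsive, heat shock, cholesterol, clock, synaptic, channel, trophic, matrix, chromatin, oxidative phosphorylation and ribosomal protein genes, and markers of neuron and other cell types. Fos, Fosb and Junb are on both the AP-1 and the immediate early list, and Dusp1, Dusp5 and Dusp6 on both the immediate early and the MAPK list. Each list was tested against all other tested genes with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and beside it with the correlation estimated and with fry. Members were also adjusted over the list alone. Named genes follow a rule also written before the data were examined: those of smallest p in each direction, the AP-1 subunits and activity genes, and the members of smallest p of each called list.

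Alternatives planned before the data were examined were median-of-ratios and upper-quartile factors, no filter, at least 50 counts in 3 libraries, DESeq2, limma-voom, a block on the replicate number, adjusted p under 0.1, each library left out in turn, a fit on all 18 libraries, a fit on the 2 groups only, and a level of at least 10 CPM for the correlation. Added after the data were seen were fits without small RNA genes and genes overlapping them, with the gene length or GC content trend removed, and with the small RNA share as covariate. Library labels were also exchanged in all 10 splits of 3 against 3 libraries and in 40 drawn splits for comparisons over both neuron types, and list scores ordered IE, SC, EE were permuted 1e+05 times within neuron types and, after the data were seen, in all 1680 arrangements that keep CA1 and DG libraries of one number together. Removing the length trend was tested on simulated data, where it took a Spearman correlation of 0.364 to 0.011.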

Results

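Nuclei of CA1 pyramidal neurons and of dentate gyrus (DG) granule neurons were compared in mice raised in an enriched (EE), standard (SC) or impoverished (IE) environment. Each of the 6 groups had n = 3 libraries, and each library pooled 3 mice. Table columns EI and NC were read as the IE and SC of the sample labels, which the files do not settle. Gene totals per library were 35144262 to 36162857 in CA1 and 34181104 to 36537887 in DG. Small RNA genes (small nucleolar, Cajal body, small nuclear and related RNAs, and Rn7sk) held 5.09 ± 0.37% of counts in CA1 EE, 5.35 ± 0.86% in CA1 SC, 4.15 ± 0.85% in CA1 IE, 4.51 ± 0.68% in DG EE, 3.79 ± 0.92% in DG SC and 5.21 ± 0.57% in DG IE (mean ± SD). In 52 of 52 pairs a host gene had at least the counts of the small RNA it contains on the same strand. Ribosomal protein genes with such RNAs in their introns may thus report both. Levels are CPM, mean ± SD over the 3 libraries of a group. Where the text says what 1 library did when left out, the number in parentheses is the list median without it, and a median is said to move where it changed by more than 1.5 times with the call kept.

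Granule neuron genes separated the 2 neuron types. Prox1 (ENSMUSG00000010175), the transcription factor that specifies granule neurons, averaged 192 ± 7.3 CPM in DG and 21 ± 9 in CA1 (9.15-fold, adjusted p = 3.96e-10), n = 9 libraries per neuron type. C1ql2, a secreted synaptic organiser of mossy fibres, was 10.3-fold higher in DG (15.6 ± 4 against 1.5 ± 0.87 CPM), Dsp 9.81-fold (45.8 ± 4.3 against 4.66 ± 2.5 CPM) and Glis3 9.77-fold (747 ± 73 against 77.1 ± 37 CPM), all at adjusted p under 0.05. In the other direction Mpped1 was 6.4-fold higher in CA1 (32.6 ± 9.6 against 207 ± 33 CPM in DG and CA1), Wfs1, an endoplasmic reticulum membrane protein of CA1 neurons, 4.35-fold (3.98 ± 0.8 against 17.3 ± 2.1 CPM), Fibcd1 4.46-fold (12.2 ± 4.2 against 53.9 ± 15 CPM) and Pex5l, which anchors HCN channels, 3.84-fold (402 ± 47 against 1540 ± 120 CPM). All 16 tested mature granule neuron markers were higher in DG, with a median log2 fold change of 3.02 (adjusted p = 7.97e-22, and still 0.0215 with an estimated correlation), and 14 of 15 CA1 markers were higher in CA1, with a median of -2.23 for DG against CA1 (adjusted p = 7.97e-22, and still 0.0115 with an estimated correlation). Rnf182 was the exception, at 83.7 ± 8.2 CPM in DG and 51.6 ± 7.9 in CA1. Smallest in p were Ston2, Apcdd1, Pnrc1, Prtg and Napepld, higher in DG 5.36, 4.87, 3.21, 2.95 and 4.05 times, and Pid1, Ppp2r2b, Pex5l, Sv2b and Etl4, higher in CA1. The edgeR test passed 10174 of 20337 genes, 4967 higher in DG and 5207 higher in CA1, 2757 of them by more than 2-fold, and DESeq2 and limma-voom called 10069 and 10126.

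**Figure D1:**
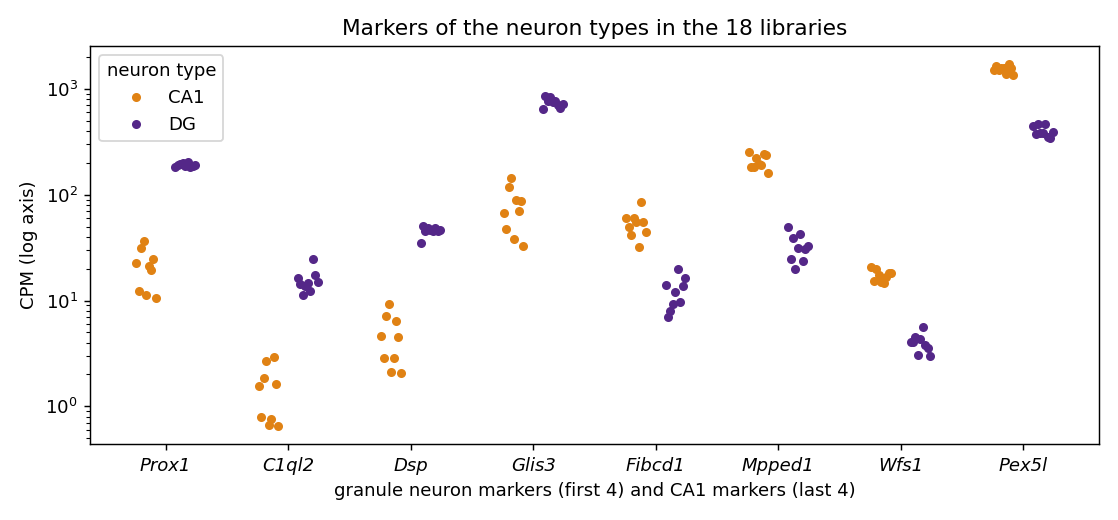
Levels of 4 granule neuron markers (Prox1, C1ql2, Dsp, Glis3) and 4 CA1 markers (Fibcd1, Mpped1, Wfs1, Pex5l) in the 18 libraries.

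Activity genes stood higher in CA1 than in DG. Nr4a2, a nuclear receptor induced by activity, averaged 7.37 ± 1.4 CPM in DG and 21.7 ± 3.9 in CA1, Plk2, a kinase of synaptic scaling, 42.6 ± 4.1 CPM in DG and 102 ± 11 in CA1, and Dusp5, a nuclear phosphatase of ERK, 4.17 ± 1.3 CPM in DG and 16.5 ± 5.1 in CA1. Over the 30 rapid immediate early genes the median was -0.94 for DG against CA1 (adjusted p = 2.43e-06, adjusted p = 0.473 with an estimated correlation), and 25 passed one by one, 3 of them higher in DG. The MAPK feedback genes were also higher in CA1 (median -0.60, adjusted p = 0.0259, adjusted p = 0.532 with an estimated correlation). Etv5 was at 28 ± 10 CPM in DG and 98.9 ± 21 in CA1. Mossy cell markers were higher in DG (median 1.86, adjusted p = 0.0205, adjusted p = 0.105 with an estimated correlation), as with the dopamine receptor gene Drd2 (3.4 ± 0.4 against 0.957 ± 0.34 CPM). CA2 markers had a median of 0.24 (adjusted p = 0.03, adjusted p = 0.216 with an estimated correlation), led by Pcp4 (54.6 ± 3.9 against 12.6 ± 2.4 CPM), and thalamic markers one of 0.81 (adjusted p = 0.0468, adjusted p = 0.741 with an estimated correlation). AP-1 subunits did not pass as a list against other genes (median -0.098, mean 0.26, adjusted p = 0.512), but did by fry (0.0215). Median and mean had opposite signs, and the test took that of the mean. Jun averaged 16.8 ± 3.8 CPM in DG and 4.71 ± 0.37 in CA1.

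Fos had higher levels in CA1 neurons of enriched than of impoverished mice, without passing alone by edgeR. Fos (ENSMUSG00000021250), the inducible subunit of the AP-1 transcription factor, averaged 2.39 ± 0.88 CPM in EE and 0.587 ± 0.46 in IE, a 4.04-fold ratio (log2 2.01, and 2.87 without IE replicate 3), and its relative Fosb (ENSMUSG00000003545) 1.71 ± 0.37 CPM in EE and 0.653 ± 0.1 in IE (2.6-fold), n = 3 libraries per group. Egr2 averaged 0.945 ± 0.2 CPM in EE and 0.25 ± 0.11 in IE (3.73-fold) and Egr1, another zinc finger factor induced by activity, 11.4 ± 1.1 CPM in EE and 6.69 ± 1.5 in IE (1.7-fold). Arc (ENSMUSG00000022602), which drives AMPA receptor endocytosis, was at 31.7 ± 8.2 CPM in EE and 14.7 ± 3 in IE (2.15-fold) and Npas4, an activity-dependent factor that shapes inhibition, at 9.77 ± 3.2 CPM in EE and 4.9 ± 0.64 in IE (1.99-fold). Outside this family, Arhgef37 (15.7 ± 1.8 against 6.94 ± 1.3 CPM) and Prkd2, a kinase of the protein kinase D family (6.31 ± 0.35 against 3.14 ± 0.42 CPM), had ratios of 2.26 and 2.01, and the neurotensin receptor gene Ntsr1 was 1.78-fold lower in EE (4.44 ± 0.5 against 7.9 ± 0.63 CPM). Pla2g7, P3h4, Ptpn14, Spata24 and SPATA24 had ratios of 1.66, 0.573, 0.639, 0.611 and 0.64. By edgeR none of these genes passed alone, though Arhgef37 had adjusted p = 0.0249 with a block on the replicate number (0.000126 to 1 over the alternatives). The smallest adjusted p was 0.256, for Fosb, Egr2, Ntsr1, Prkd2 and Arhgef37. Of 19449 genes, 0 passed by edgeR and 926 had an unadjusted p under 0.05, where 972 would by chance. DESeq2 called 20 (16 higher, 4 lower), among them Fosb, Egr2, Fos, Arc, Egr1 and Npas4, and limma-voom 0.

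As a list, the rapid immediate early genes rose in EE. All 30 were higher, by a median log2 fold change of 0.46 (adjusted p = 2.48e-32, adjusted p = 0.186 with an estimated correlation, 1.38e-42 to 0.271 over the alternatives), with 14 past the threshold adjusted over the list alone and 16 at an unadjusted p under 0.05. AP-1 subunits rose by a median of 0.14 and a mean of 0.44, the mean resting on Fos and Fosb, while Junb averaged 5.21 ± 1.5 CPM in EE and 3.89 ± 1.2 in IE and Jun 4.9 ± 0.33 CPM in EE and 4.48 ± 0.19 in IE (adjusted p = 9.22e-05, adjusted p = 0.24 with an estimated correlation, 3.67e-06 to 0.274 over the alternatives), and 7 of 9 were higher, 2 of which passed adjusted over the list alone. MAPK feedback genes, which damp ERK signalling, rose by a median of 0.24 (adjusted p = 2.84e-07, adjusted p = 0.24 with an estimated correlation, 1.4e-10 to 0.274 over the alternatives). Dusp5 was at 21.5 ± 4.9 CPM in EE and 12.1 ± 3.1 in IE and Etv5 at 115 ± 26 CPM in EE and 77.5 ± 7.8 in IE. The MAPK list had 2 past the threshold adjusted over the list alone and 4 at an unadjusted p under 0.05. Delayed activity-regulated genes, glucocorticoid-responsive genes and heat shock genes rose too, by medians of 0.13, 0.13 and 0.18 (19 of 27, 15 of 15 and 18 of 19 members higher). Adjusted p was 0.00291, 0.00291 and 5.94e-05, and 0.359, 0.304 and 0.423 with an estimated correlation. Those 3 lists had 0, 0 and 0 members past the threshold adjusted over the list alone by edgeR (4, 1 and 4 at an unadjusted p under 0.05), and their adjusted p ran 7.97e-05 to 0.368, 0.000776 to 0.304 and 1.45e-08 to 0.423 over the alternatives. Among them, the scaffold gene Homer1 averaged 495 ± 68 CPM in EE and 348 ± 130 in IE, the clock gene Per1 30.1 ± 9.1 CPM in EE and 22.8 ± 4.6 in IE and the co-chaperone gene Bag3 3 ± 1.2 CPM in EE and 1.82 ± 0.2 in IE. Per1 is also on the immediate early list. The AP-1 median moved without EE replicate 2 (0.22). The delayed call ended without IE replicate 2 (0.10), its median moving without IE replicate 3 (0.20). The glucocorticoid call ended without IE replicate 3 (0.09), its median moving without IE replicate 1 (0.20). The heat shock call ended without IE replicate 2 (0.063), its median moving without IE replicate 3 (0.35).

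Oligodendrocyte genes rose and CA2 markers fell in CA1 EE against IE. Oligodendrocyte genes rose by a median of 0.26 (adjusted p = 7.82e-05, adjusted p = 0.265 with an estimated correlation, 1.14e-06 to 0.274 over the alternatives). Mobp was at 10.3 ± 1.6 CPM in EE and 7.53 ± 0.42 in IE. CA2 markers fell, all 7 lower in EE, with a median of -0.29 (adjusted p = 0.00291, adjusted p = 0.265 with an estimated correlation, 0.00201 to 0.274 over the alternatives), with Rgs14, a suppressor of CA2 plasticity, at 20.2 ± 3.4 CPM in EE and 26.1 ± 4.9 in IE. Immature granule neuron markers such as Dcx (33.7 ± 4.1 against 40.7 ± 9.1 CPM) fell with a median of -0.22 (adjusted p = 0.0357, adjusted p = 0.563 with an estimated correlation, 0.00774 to 0.673 over the alternatives). Ribosomal protein genes rose by a median of 0.058 (adjusted p = 0.0174, adjusted p = 0.926 with an estimated correlation, 4.41e-06 to 0.926 over the alternatives), but the 25 members that contain a small nucleolar RNA had a median of 0.29 and the other 57 one of -0.039. Rpl10, which contains Snora70, averaged 61.9 ± 7.5 CPM in EE and 42.6 ± 8.5 in IE. These 4 lists had 0, 0, 0 and 0 members past the threshold adjusted over the list alone by edgeR (3, 2, 0 and 7 at an unadjusted p under 0.05). The immature granule call ended without EE replicate 3 (-0.28) and IE replicate 3 (-0.11), its median moving without IE replicate 2 (-0.14). The ribosomal protein call ended without EE replicate 2 (0.002) and IE replicates 2 (0.015) and 3 (0.047), its median moving without IE replicate 1 (0.088).

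Arc was among the genes of smallest p between enriched and impoverished rearing in DG granule neurons. It averaged 10.7 ± 2.4 CPM in EE and 4.67 ± 0.84 in IE, a 2.29-fold ratio with adjusted p = 0.186, n = 3 libraries per group. Fos was at 1.01 ± 0.064 CPM in EE and 0.407 ± 0.063 in IE (2.48-fold), the nuclear receptor gene Nr4a1 at 19.6 ± 5.6 CPM in EE and 11.4 ± 2.4 in IE (1.72-fold) and Dusp5 (ENSMUSG00000034765) at 5.77 ± 1.2 CPM in EE and 3.18 ± 0.081 in IE (1.82-fold). Lhfp (ENSMUSG00000048332) averaged 28.4 ± 1.9 CPM in EE and 16.6 ± 1.2 in IE. Pid1 (ENSMUSG00000045658) averaged 80.9 ± 7 CPM in EE and 54.2 ± 4.1 in IE. Etl4 and Rasgef1b had ratios of 1.62 and 1.55. Pid1 and Etl4 were higher in CA1 than in DG, so more CA1 nuclei in DG EE libraries may add to both, to an untested extent. Igfbp5 was 1.46-fold lower in EE (41.9 ± 3.8 against 61.1 ± 4.3 CPM), as were the fructose kinase gene Khk (2.71 ± 0.25 against 4.46 ± 0.46 CPM) and Rsrp1 (54.1 ± 1.7 against 72.1 ± 7.3 CPM), with ratios of 0.583 and 0.622 for Vwa5b1 and Cstad. Of 19465 genes, 0 passed by edgeR and 1533 had an unadjusted p under 0.05, where 973 would by chance. DESeq2 called 45 (35 higher, 10 lower), Arc, Nr4a1 and Dusp5 among them, and limma-voom 0. Without DG EE replicate 3 edgeR called 1 gene, Arc.

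**Figure D2:**
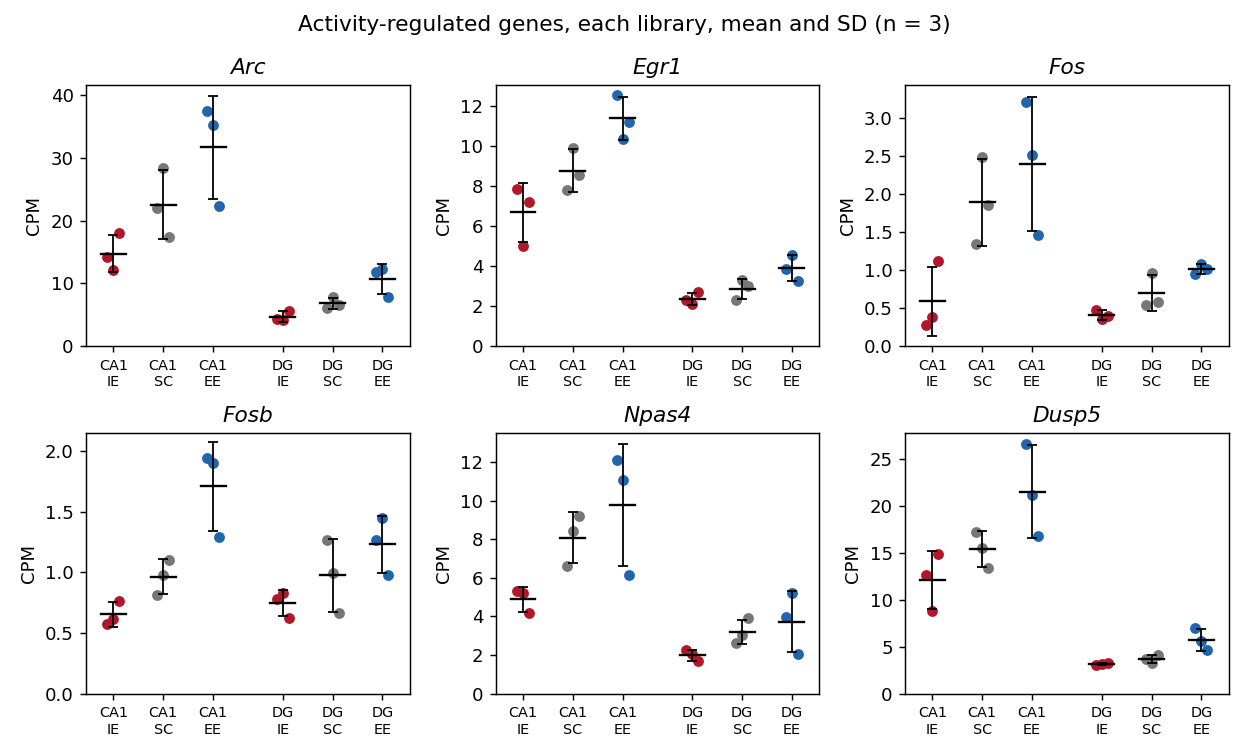
Levels of Arc, Egr1, Fos, Fosb, Npas4 and Dusp5 in each library by neuron type and rearing condition. None passed the threshold alone by edgeR in a rearing comparison.

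Activity programmes rose in DG EE against IE. The rapid immediate early genes were higher in 22 of 28 cases, by a median of 0.27 (adjusted p = 5.84e-09, adjusted p = 0.206 with an estimated correlation, 1.33e-16 to 0.206 over the alternatives), with 6 past the threshold adjusted over the list alone and 12 at an unadjusted p under 0.05. MAPK feedback genes rose by a median of 0.22 (adjusted p = 4.78e-05, adjusted p = 0.155 with an estimated correlation, 6.13e-07 to 0.167 over the alternatives). Etv5 was at 37.2 ± 13 CPM in EE and 20.7 ± 6.1 in IE and Spred1 at 92.1 ± 19 CPM in EE and 68.3 ± 7.6 in IE. Delayed genes and heat shock genes rose by medians of 0.15 and 0.12 (17 of 27 and 13 of 18 members higher). Adjusted p was 0.0109 and 0.0181, and 0.223 and 0.516 with an estimated correlation. The prohormone convertase gene Pcsk1 was at 21.7 ± 7 CPM in EE and 12.8 ± 1 in IE and the sorting receptor gene Sorcs3 at 236 ± 18 CPM in EE and 170 ± 20 in IE. The MAPK, delayed and heat shock lists had 1, 5 and 0 members past the threshold adjusted over the list alone by edgeR (6, 8 and 2 at an unadjusted p under 0.05), 2 of the 5 delayed ones being lower in EE, and the latter 2 lists an adjusted p of 0.00253 to 0.223 and 0.000305 to 0.516 over the alternatives. AP-1 subunits did not pass as a list (median 0.13, 6 of 10 higher, adjusted p = 0.0576, adjusted p = 0.516 with an estimated correlation, 0.00532 to 0.642 over the alternatives), but 5 passed adjusted over the list alone, 4 higher and Jun lower, at 15.3 ± 2.7 CPM in EE and 20.9 ± 4.1 in IE. The AP-1 list did pass without DG EE replicate 3 (0.22) or DG IE replicate 1 (0.34). The immediate early median moved without EE replicate 1 (0.14). The MAPK feedback median moved without EE replicate 1 (0.099). The delayed call ended without EE replicate 3 (0.12) and IE replicate 1 (0.11). The heat shock call ended without EE replicates 1 (0.13) and 2 (0.12) and IE replicates 1 (0.092) and 2 (0.083).

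Synaptic genes rose in the granule neurons of enriched mice. Metabotropic glutamate receptors were all higher (7 of 7, median 0.34, adjusted p = 0.000326, adjusted p = 0.155 with an estimated correlation, 2.61e-05 to 0.203 over the alternatives), with 3 past the threshold adjusted over the list alone and 3 at an unadjusted p under 0.05. Grm4, a presynaptic receptor, averaged 12.7 ± 3.9 CPM in EE and 7.93 ± 1.4 in IE and Grm8 172 ± 57 CPM in EE and 111 ± 8.2 in IE. Ionotropic glutamate receptors, GABA-A receptor subunits and calcium and sodium channels rose by medians of 0.12, 0.14 and 0.094 (24 of 29, 11 of 12 and 18 of 23 members higher). Adjusted p was 0.000986, 0.0181 and 0.0181, and 0.326, 0.516 and 0.371 with an estimated correlation. The kainate receptor gene Grik1 averaged 62.6 ± 16 CPM in EE and 43 ± 5.7 in IE and the calcium channel subunit gene Cacna2d3 897 ± 19 CPM in EE and 761 ± 62 in IE. Postsynaptic scaffolds, presynaptic release genes and trophic factors rose by medians of 0.13, 0.12 and 0.16 (20 of 28, 23 of 32 and 14 of 20 members higher). Adjusted p was 0.00241, 0.0181 and 0.00671, and 0.326, 0.155 and 0.155 with an estimated correlation. Lrrtm3 averaged 183 ± 35 CPM in EE and 127 ± 2.7 in IE, the vesicular glutamate transporter gene Slc17a6 8.3 ± 4.2 CPM in EE and 3.38 ± 0.79 in IE and Nrg1, which signals through ERBB4, 777 ± 130 CPM in EE and 571 ± 15 in IE. These last 6 lists had 0, 0, 0, 0, 0 and 0 members past the threshold adjusted over the list alone by edgeR (3, 3, 3, 4, 4 and 3 at an unadjusted p under 0.05), and an adjusted p of 3.33e-05 to 0.326, 0.00137 to 0.813, 0.00226 to 0.471, 4.5e-06 to 0.326, 0.00298 to 0.33 and 0.00273 to 0.33 over the alternatives. With the gene length trend removed, 1 of the 7 lists, the metabotropic receptors, passed (median 0.144, adjusted p = 0.0144). Gene length and fold change were correlated in this comparison (Spearman 0.272 over 15557 genes, which are not independent replicates), and 28 members at least 1.5 times as high in CA1 as in DG had a larger median (0.265) than the other 123 (0.11). The ionotropic call ended without IE replicate 3 (0.10). The metabotropic median moved without EE replicate 3 (0.14). The GABA-A call ended without EE replicate 3 (-0.012) and IE replicates 1 (0.10) and 2 (0.14), its median moving without EE replicate 1 (0.24) and IE replicate 3 (0.24). The channel call ended without EE replicate 1 (0.079) and IE replicate 3 (0.066). The postsynaptic call ended without EE replicate 1 (0.025) and IE replicate 3 (0.058). The presynaptic call ended without IE replicate 3 (0.086). The trophic call ended without EE replicate 2 (0.10).

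**Figure D3:**
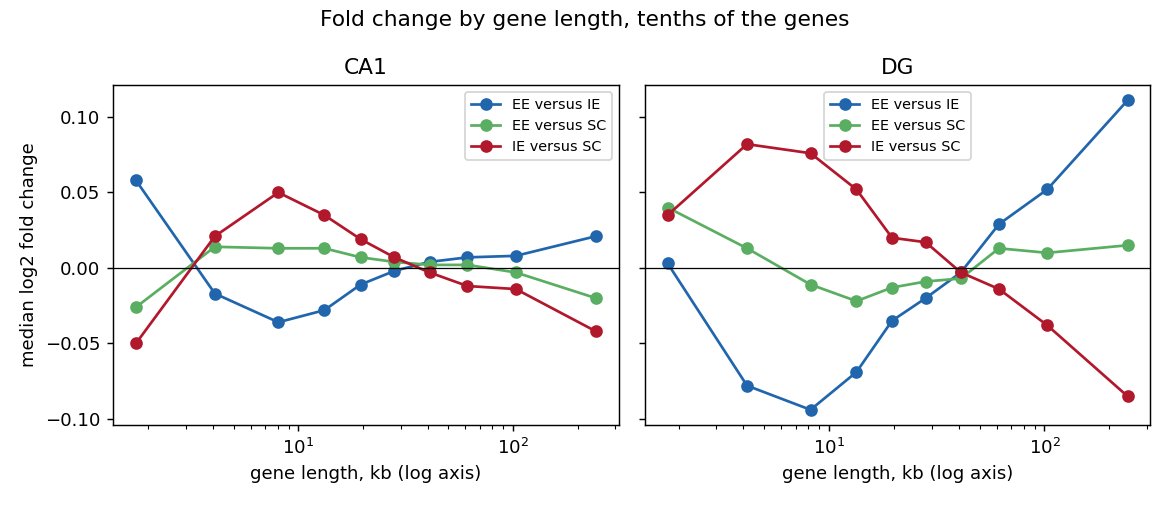
Median log2 fold change by gene length for the 6 rearing comparisons. Long genes were higher in DG EE than in DG IE and lower in DG IE than in DG SC.

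CA2 and microglial markers fell in DG EE against IE and CA1 markers rose. Amigo2, a CA2 adhesion protein gene, averaged 2.85 ± 0.68 CPM in EE and 4.2 ± 0.4 in IE and Rgs14 15.5 ± 3.2 CPM in EE and 20.5 ± 1.6 in IE, and all 7 CA2 markers were lower (median -0.34, adjusted p = 0.0035, adjusted p = 0.155 with an estimated correlation, 0.000877 to 0.167 over the alternatives). Microglial genes fell with a median of -0.18 (adjusted p = 0.0181, adjusted p = 0.437 with an estimated correlation, 0.00346 to 0.437 over the alternatives). Trem2 was at 0.421 ± 0.1 CPM in EE and 0.7 ± 0.12 in IE. CA1 markers rose by a median of 0.20 (adjusted p = 0.0181, adjusted p = 0.516 with an estimated correlation, 0.000185 to 0.547 over the alternatives). Ribosomal protein genes fell with a median of -0.15 (72 of 82 lower, adjusted p = 4.34e-07, adjusted p = 0.516 with an estimated correlation, 4.71e-11 to 0.516 over the alternatives). Rps14 was at 11.8 ± 0.93 CPM in EE and 14.8 ± 1.2 in IE. The 4 lists had 2, 0, 0 and 0 members past the threshold adjusted over the list alone by edgeR (2, 2, 1 and 9 at an unadjusted p under 0.05). The CA2 marker median moved without IE replicate 1 (-0.09). The microglia call ended without EE replicate 1 (-0.13) and IE replicate 3 (-0.20), its median moving without EE replicate 2 (-0.29). The CA1 marker call ended without EE replicates 1 (0.12) and 3 (0.16) and IE replicates 1 (0.15) and 2 (0.17), its median moving without IE replicate 3 (0.32).

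Fos, Fosb, Arc, Egr1, Npas4 and Dusp5 stood higher in EE than in IE in both neuron types, with ratios of 4.04, 2.6, 2.15, 1.7, 1.99 and 1.78 in CA1 (Fos at log2 2.87 instead of 2.01 without IE replicate 3) and 2.48, 1.65, 2.29, 1.65, 1.87 and 1.82 in DG. Jun did not follow them, at a 1.09-fold ratio in CA1 and 0.733 in DG, and Bdnf stood at 1.23 and 1.16. Over 18749 genes tested in both, the EE against IE effects correlated at Pearson 0.298 (Spearman 0.362), and 65.4% had the same sign. Genes are not independent replicates, and 20 of 100 pairs of library splits gave a correlation as large, the highest other 0.598. CA1 and DG libraries of one number were correlated too (mean 0.383), which this comparison ignores. Without CA1 IE replicate 1 the correlation was 0.173. At an unadjusted p under 0.05, CA1 and DG shared 71 genes higher in EE (of 462 and 739) and 99 lower (of 416 and 746). Chance would give 18.2 and 16.6 only for independent genes and libraries, and exchanged labels were not tried here.

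Pla2g7 had the smallest adjusted p between enriched and standard rearing in CA1. Pla2g7 (ENSMUSG00000023913) averaged 5.98 ± 0.7 CPM in EE and 2.82 ± 0.17 in SC (2.12-fold, adjusted p = 0.143), n = 3 libraries per group. The protease gene Prss41 was 7.19-fold lower in EE at a low level (0.161 ± 0.14 against 1.19 ± 0.41 CPM, log2 -2.85, and -3.51 without EE replicate 1), Dbp 1.62-fold lower (5.07 ± 0.3 against 8.2 ± 0.39 CPM), and Kcnj10, the glial potassium channel Kir4.1, 1.68-fold higher (2.59 ± 0.3 against 1.54 ± 0.12 CPM). Ratios of Daam2, Rarb, Mthfd1l and Snora64 were 1.42, 0.729, 0.753 and 0.664. Arc averaged 31.7 ± 8.2 CPM in EE and 22.6 ± 5.5 in SC and Fos 2.39 ± 0.88 CPM in EE and 1.89 ± 0.57 in SC. Of 19449 genes, 0 passed by edgeR and 416 had an unadjusted p under 0.05, where 972 would by chance. DESeq2 called 2 (Pla2g7 higher, Prss41 lower), and limma-voom 0.

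Oligodendrocyte genes rose in CA1 EE against SC, in libraries of sorted neuronal nuclei. Whether the share of non-neuronal nuclei differed between these libraries was not tested. Mag (ENSMUSG00000036634), a myelin adhesion gene, averaged 4.92 ± 0.83 CPM in EE and 2.87 ± 0.57 in SC, Mobp 10.3 ± 1.6 CPM in EE and 6.72 ± 1.1 in SC and Aspa, which breaks down N-acetylaspartate, 2.38 ± 0.5 CPM in EE and 1.42 ± 0.088 in SC, and all 16 were higher, by a median of 0.46 (adjusted p = 9.86e-23, and still 0.0297 with an estimated correlation, 8.7e-26 to 0.126 over the alternatives), 3 past the threshold adjusted over the list alone and 9 at an unadjusted p under 0.05. By fry the list had adjusted p = 0.126. Oligodendrocyte precursor, astrocyte and microglial genes rose by medians of 0.21, 0.21 and 0.26 (10 of 10, 12 of 15 and 12 of 14 members higher). Adjusted p was 0.000186, 0.00179 and 0.00179, and 0.376, 0.413 and 0.481 with an estimated correlation. Gpr17 was at 1.93 ± 0.34 CPM in EE and 1.15 ± 0.27 in SC, the connexin gene Gja1 at 2.6 ± 0.16 CPM in EE and 1.81 ± 0.14 in SC and C1qa at 0.656 ± 0.3 CPM in EE and 0.395 ± 0.14 in SC. Adjusted p of these lists ran 1.02e-05 to 0.64, 1.61e-05 to 0.667 and 3.8e-07 to 0.717 over the alternatives. CA1 markers and interneuron markers rose by medians of 0.047 and 0.067 (11 of 15 and 11 of 16 members higher). Adjusted p was 0.0424 and 0.0415, and 0.462 and 0.482 with an estimated correlation. CA2 markers fell with a median of -0.18 (adjusted p = 0.017, adjusted p = 0.376 with an estimated correlation, 0.000858 to 0.64 over the alternatives). Pvalb averaged 0.908 ± 0.13 CPM in EE and 0.491 ± 0.17 in SC. The CA1 and interneuron lists had an adjusted p of 0.00701 to 0.715 and 0.0242 to 0.717 over the alternatives. The latter 6 lists had 0, 0, 0, 0, 0 and 0 members past the threshold adjusted over the list alone by edgeR (2, 2, 0, 1, 1 and 0 at an unadjusted p under 0.05). The precursor median moved without SC replicates 1 (0.45) and 2 (0.12). The astrocyte call ended without EE replicate 3 (0.10) and SC replicate 3 (0.11), its median moving without EE replicate 2 (0.32). The microglia call ended without EE replicate 1 (0.097) and SC replicate 3 (0.12), its median moving without SC replicates 1 (0.68) and 2 (0.16). The CA1 marker call ended without EE replicates 1 (0.047) and 2 (0.052) and SC replicate 3 (-0.026), its median moving without EE replicate 3 (0.11) and SC replicates 1 (0.099) and 2 (0.13). The interneuron call ended without EE replicates 1 (0.07) and 3 (0.094) and SC replicates 1 (0.13) and 3 (0.068), its median moving without SC replicate 2 (0.042). The CA2 marker call ended without EE replicate 1 (-0.20) and SC replicate 1 (-0.14), its median moving without EE replicates 2 (-0.12) and 3 (-0.11) and SC replicate 2 (-0.32).

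Activity genes rose in CA1 EE against SC with smaller medians than against IE. The rapid immediate early genes rose by a median of 0.23 (24 of 30 higher, adjusted p = 4.09e-09, adjusted p = 0.376 with an estimated correlation, 5.23e-15 to 0.659 over the alternatives). Egr2 was at 0.945 ± 0.2 CPM in EE and 0.511 ± 0.032 in SC, Fosb at 1.71 ± 0.37 CPM in EE and 0.964 ± 0.15 in SC and Egr1 at 11.4 ± 1.1 CPM in EE and 8.77 ± 1.1 in SC. AP-1 subunits did not pass (median 0.051, 5 of 9 higher, adjusted p = 0.148, adjusted p = 0.481 with an estimated correlation, 0.0172 to 0.834 over the alternatives), but did without EE replicate 3 (0.045) or SC replicate 2 (0.17). Delayed genes, MAPK feedback genes and heat shock genes rose by medians of 0.099, 0.12 and 0.13 (20 of 27, 13 of 16 and 17 of 19 members higher). Adjusted p was 0.000629, 0.00291 and 0.000144, and 0.376, 0.413 and 0.413 with an estimated correlation. The pentraxin gene Nptx2 averaged 8.64 ± 1.6 CPM in EE and 5.68 ± 1.5 in SC. Cholesterol biosynthesis genes and clock genes fell, with medians of -0.094 and -0.078 (15 of 20 and 13 of 18 members lower). Adjusted p was 0.0162 and 0.0137, and 0.477 and 0.376 with an estimated correlation. Nr1d2 was at 55.1 ± 2.7 CPM in EE and 66.1 ± 6.6 in SC. Oxidative phosphorylation genes rose by a median of 0.045 (adjusted p = 0.0187, 0.559 with an estimated correlation, 0.000858 to 0.717 over the alternatives). The 7 lists had 0, 0, 0, 0, 0, 1 and 0 members past the threshold adjusted over the list alone by edgeR (5, 3, 1, 1, 0, 3 and 0 at an unadjusted p under 0.05), and the delayed, MAPK, heat shock, cholesterol and clock lists an adjusted p of 0.00012 to 0.64, 0.000297 to 0.667, 1.03e-05 to 0.667, 0.00158 to 0.667 and 0.00211 to 0.64 over the alternatives. The immediate early median moved without EE replicate 1 (0.075) and SC replicates 2 (0.36) and 3 (0.15). The delayed median moved without EE replicate 1 (0.053) and SC replicate 2 (0.17). The MAPK feedback call ended without EE replicate 1 (0.014). The cholesterol call ended without EE replicate 2 (-0.011) and SC replicates 2 (-0.10) and 3 (-0.099), its median moving without EE replicate 1 (-0.16). The clock call ended without EE replicate 2 (-0.028) and SC replicate 3 (-0.068), its median moving without EE replicate 1 (-0.17). The oxidative phosphorylation call ended without EE replicates 2 (0.049) and 3 (0.047) and SC replicates 1 (0.019) and 3 (0.054), its median moving without EE replicate 1 (0.069) and SC replicate 2 (0.088).

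Fos was lower in CA1 neurons of impoverished than of standard mice. It averaged 0.587 ± 0.46 CPM in IE and 1.89 ± 0.57 in SC (3.19-fold lower, log2 -1.67, and -2.53 without IE replicate 3), Npas4 4.9 ± 0.64 CPM in IE and 8.07 ± 1.3 in SC (1.65-fold), Egr2 0.25 ± 0.11 CPM in IE and 0.511 ± 0.032 in SC and Btg2, an antiproliferative early gene, 2.87 ± 0.24 CPM in IE and 4.6 ± 1 in SC, n = 3 libraries per group. Arhgef37 (ENSMUSG00000045094) was 2.48-fold lower (6.94 ± 1.3 against 17.2 ± 4.5 CPM, adjusted p = 0.347, 0.0103 with a block on the replicate number and 1.75e-05 to 1 over the alternatives), and Ntsr1 1.5-fold higher (7.9 ± 0.63 against 5.26 ± 0.12 CPM). Fam122a, Fign, Fam210b and Wdr6 had ratios of 2.45, 2.13, 1.39 and 1.37. The small nucleolar RNAs Snora64 (26.7 ± 5.2 against 51.9 ± 8.2 CPM), Snora34 (33.8 ± 7.4 against 68.9 ± 19 CPM) and Snora21 (43.8 ± 8.5 against 79.5 ± 15 CPM) were 1.94-, 2.03- and 1.82-fold lower in IE, and so was Rps2, which contains Snora64 (28.4 ± 5.6 against 53.9 ± 8.5 CPM). Of 19449 genes, 0 passed by edgeR and 784 had an unadjusted p under 0.05, where 972 would by chance. DESeq2 called 69 (1 higher, 68 lower), 64 of which were small RNA genes or genes overlapping them, and limma-voom 0.

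Rapid immediate early genes fell in CA1 IE against SC. In all, 26 of 30 were lower, with a median of -0.37 (adjusted p = 3.62e-11, adjusted p = 0.516 with an estimated correlation, 1.1e-15 to 0.69 over the alternatives). AP-1 subunits and MAPK feedback genes fell, with medians of -0.089 and -0.14 (6 of 9 and 14 of 16 members lower). Adjusted p was 0.0146 and 0.0179, and 0.516 and 0.664 with an estimated correlation. Fosb was at 0.653 ± 0.1 CPM in IE and 0.964 ± 0.15 in SC and Dusp1, which dephosphorylates MAP kinases, at 3.06 ± 0.31 CPM in IE and 4.21 ± 1.2 in SC. Clock genes fell with a median of -0.12 (adjusted p = 0.0267, adjusted p = 0.516 with an estimated correlation, 0.00308 to 0.69 over the alternatives). Per2 was at 35 ± 3.1 CPM in IE and 45 ± 8.1 in SC. The AP-1 and MAPK lists had an adjusted p of 0.00247 to 0.69 and 3.84e-05 to 0.7 over the alternatives, and the 4 lists had 0, 1, 0 and 0 members past the threshold adjusted over the list alone by edgeR (9, 2, 2 and 2 at an unadjusted p under 0.05). The immediate early median moved without SC replicate 2 (-0.24). The AP-1 call ended without IE replicates 2 (-0.14) and 3 (-0.067) and SC replicate 2 (-0.033), its median moving without IE replicate 1 (-0.32) and SC replicates 1 (-0.022) and 3 (-0.15). The MAPK feedback call ended without IE replicate 2 (-0.068) and SC replicates 1 (-0.094) and 2 (-0.13), its median moving without IE replicate 3 (-0.25). The clock call ended without IE replicate 3 (-0.15) and SC replicates 1 (-0.12) and 3 (-0.024), its median moving without IE replicate 1 (-0.07).

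Glial genes rose in CA1 IE against SC. Microglial genes had a median of 0.37 (adjusted p = 0.000505, adjusted p = 0.664 with an estimated correlation, 1.39e-07 to 0.739 over the alternatives). Siglech was at 1.37 ± 0.57 CPM in IE and 0.743 ± 0.39 in SC. Astrocyte, oligodendrocyte and precursor genes rose by medians of 0.32, 0.22 and 0.18 (13 of 15, 15 of 16 and 8 of 10 members higher). Adjusted p was 0.000505, 0.000224 and 0.0293, and 0.516, 0.516 and 0.664 with an estimated correlation. The glutamate transporter gene Slc1a3 averaged 14.5 ± 2.1 CPM in IE and 10.5 ± 2.6 in SC and Myrf, the regulator of myelin genes, 7.31 ± 1.7 CPM in IE and 5.3 ± 0.82 in SC. Adjusted p of these lists ran 1.72e-05 to 0.7, 9.84e-06 to 0.69 and 0.00224 to 0.7 over the alternatives. Ribosomal protein genes fell with a median of -0.06 (adjusted p = 9.03e-05, adjusted p = 0.686 with an estimated correlation, 2.8e-10 to 0.7 over the alternatives). All 25 members with a small nucleolar RNA were lower (median -0.492), as with Rps3, which contains Snord15a and Snord15b (1430 ± 310 against 2370 ± 480 CPM), while the other 57 had a median of 0.038 and 268 of 287 small nucleolar RNAs were lower (median -0.69). The 5 lists had 0, 0, 0, 0 and 7 members past the threshold adjusted over the list alone by edgeR (0, 2, 2, 1 and 18 at an unadjusted p under 0.05). The microglia call ended without IE replicate 1 (0.15) and SC replicate 3 (0.25), its median moving without IE replicate 3 (0.58) and SC replicate 1 (0.80). The astrocyte call ended without IE replicate 3 (0.24), its median moving without SC replicate 3 (0.18). The oligodendrocyte median moved without SC replicate 3 (0.13). The precursor call ended without IE replicate 1 (-0.032) and SC replicates 2 (0.19) and 3 (0.18), its median moving without IE replicate 3 (0.31) and SC replicate 1 (0.42). The ribosomal protein call ended without SC replicate 2 (0.018), its median moving without IE replicates 1 (-0.11) and 2 (-0.018).

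Klf5 was among the genes of smallest p between enriched and standard rearing in DG. Klf5 (ENSMUSG00000005148) averaged 4.08 ± 0.38 CPM in EE and 1.62 ± 0.7 in SC (2.51-fold, adjusted p = 0.513), n = 3 libraries per group. Ldb2 averaged 177 ± 47 CPM in EE and 93.1 ± 13 in SC, Lbh 4.34 ± 0.44 CPM in EE and 2.31 ± 0.51 in SC, Pappa 12.7 ± 2.5 CPM in EE and 7.6 ± 0.49 in SC, and Lhfp 28.4 ± 1.9 CPM in EE and 18.4 ± 2.7 in SC. Wnt9a was 1.87-fold lower (3.53 ± 0.37 against 6.61 ± 0.21 CPM), as were the transcription factor gene Onecut1 (6.86 ± 0.77 against 10.4 ± 1.9 CPM) and Prss41 (0.167 ± 0.16 against 0.794 ± 0.24 CPM, log2 -2.24, and -3.12 and -1.65 without EE replicates 1 and 2), with ratios of 0.278 and 0.756 for Slc26a3 and Glo1. Of 19465 genes, 0 passed by edgeR and 978 had an unadjusted p under 0.05, where 973 would by chance. DESeq2 called 23 (19 higher, 4 lower), and limma-voom 0. Without DG EE replicate 2 edgeR called 2 genes, Ldb2 among them.

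Activity lists rose in DG EE against SC. The rapid immediate early genes rose by a median of 0.29 (22 of 28 higher, adjusted p = 6.34e-06, adjusted p = 0.283 with an estimated correlation, 4.26e-11 to 0.283 over the alternatives). Arc was at 10.7 ± 2.4 CPM in EE and 6.81 ± 0.88 in SC, Nr4a1 at 19.6 ± 5.6 CPM in EE and 13.8 ± 0.41 in SC and Dusp5 at 5.77 ± 1.2 CPM in EE and 3.69 ± 0.43 in SC. AP-1 subunits, delayed genes and MAPK feedback genes rose by medians of 0.29, 0.15 and 0.13 (8 of 10, 23 of 27 and 13 of 17 members higher). Adjusted p was 0.0135, 0.00138 and 0.0112, and 0.407, 0.232 and 0.283 with an estimated correlation. Atf3, a stress-induced partner of AP-1, averaged 0.486 ± 0.079 CPM in EE and 0.281 ± 0.076 in SC and the neuropeptide precursor gene Vgf 6.31 ± 1.7 CPM in EE and 4.05 ± 0.67 in SC. Metabotropic glutamate receptors, trophic factors and heat shock genes rose by medians of 0.13, 0.12 and 0.099 (6 of 7, 18 of 20 and 15 of 18 members higher). Adjusted p was 0.0135, 0.00747 and 0.0416, and 0.283, 0.225 and 0.6 with an estimated correlation. Grm4 averaged 12.7 ± 3.9 CPM in EE and 7.33 ± 1.8 in SC and Nrg1 777 ± 130 CPM in EE and 599 ± 96 in SC. These 7 lists had 2, 0, 0, 1, 2, 0 and 0 members past the threshold adjusted over the list alone by edgeR (9, 2, 6, 2, 2, 5 and 0 at an unadjusted p under 0.05), and the latter 6 an adjusted p of 0.00115 to 0.407, 0.000434 to 0.232, 0.00115 to 0.348, 0.00348 to 0.307, 0.00272 to 0.225 and 0.0108 to 0.6 over the alternatives. The immediate early median moved without EE replicate 1 (0.19) and SC replicate 1 (0.16). The AP-1 call ended without EE replicates 1 (0.25) and 2 (0.23) and SC replicate 3 (0.18). The delayed call ended without EE replicate 3 (0.053). The MAPK feedback call ended without EE replicate 1 (0.032) and SC replicate 2 (0.11). The metabotropic call ended without EE replicate 3 (0.035) and SC replicate 3 (0.062), its median moving without EE replicate 1 (0.22) and SC replicate 1 (0.21). The trophic call ended without EE replicate 2 (0.096) and SC replicate 2 (0.12), its median moving without EE replicate 3 (0.061) and SC replicate 3 (0.055). The heat shock call ended without EE replicates 1 (0.079) and 2 (0.13) and SC replicates 1 (0.072) and 2 (0.10).

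Interneuron and oligodendrocyte genes rose in DG EE against SC. The GABA synthesis gene Gad2 averaged 11.2 ± 1 CPM in EE and 8.69 ± 0.84 in SC and Nxph1 59.5 ± 11 CPM in EE and 41.7 ± 8.4 in SC, with a median of 0.38 over the interneuron list (adjusted p = 6.37e-06, adjusted p = 0.225 with an estimated correlation, 1.1e-07 to 0.225 over the alternatives). Oligodendrocyte and precursor genes rose by medians of 0.35 and 0.33 (14 of 16 and 9 of 10 members higher). Adjusted p was 2.2e-07 and 0.0011, and 0.236 and 0.242 with an estimated correlation. Mobp was at 6.75 ± 1 CPM in EE and 4.88 ± 0.77 in SC and the proteoglycan gene Cspg4 at 3.19 ± 0.086 CPM in EE and 2.21 ± 0.52 in SC. Adjusted p of these lists ran 1.1e-08 to 0.236 and 3.58e-05 to 0.26 over the alternatives. CA2 markers fell with a median of -0.17 (adjusted p = 0.0135, adjusted p = 0.242 with an estimated correlation, 0.0059 to 0.277 over the alternatives), and ribosomal protein genes rose by a median of 0.081 (adjusted p = 0.00995, adjusted p = 0.789 with an estimated correlation, 1.1e-07 to 0.789 over the alternatives), with 25 host members at a median of 0.176 and the other 57 at 0.05. With the small RNA share as covariate the ribosomal protein median was -0.037 (adjusted p = 0.416), of the other sign. The 5 lists had 0, 0, 0, 0 and 0 members past the threshold adjusted over the list alone by edgeR (5, 8, 4, 1 and 1 at an unadjusted p under 0.05). The oligodendrocyte median moved without EE replicate 3 (0.20). The precursor call ended without EE replicate 2 (0.29). The CA2 marker call ended without EE replicate 3 (-0.16) and SC replicate 1 (-0.14). The ribosomal protein call ended without EE replicates 1 (0.02) and 2 (0.069) and SC replicate 1 (0.011), its median moving without EE replicate 3 (0.12) and SC replicate 2 (0.18).

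Postsynaptic genes fell in DG granule neurons of impoverished against standard mice. Dlgap1, a scaffold of the postsynaptic density, averaged 2110 ± 85 CPM in IE and 2520 ± 210 in SC and Camk2a, its major kinase, 809 ± 58 CPM in IE and 954 ± 120 in SC, n = 3 libraries per group, and 24 of 28 scaffold genes were lower (median -0.13, adjusted p = 8.86e-05, adjusted p = 0.382 with an estimated correlation, 2.32e-07 to 0.382 over the alternatives). Ionotropic glutamate receptors, calcium and sodium channels and chromatin modifiers fell, with medians of -0.10, -0.078 and -0.047 (24 of 29, 18 of 23 and 29 of 40 members lower). Adjusted p was 0.000613, 0.00944 and 0.0479, and 0.382, 0.382 and 0.455 with an estimated correlation. Grin2a, an NMDA receptor gene, averaged 2420 ± 220 CPM in IE and 2920 ± 330 in SC and the acetyltransferase gene Crebbp 263 ± 16 CPM in IE and 292 ± 8.1 in SC. Adjusted p of these lists ran 2.14e-05 to 0.487, 0.000783 to 0.487 and 0.00472 to 0.548 over the alternatives. Oxidative phosphorylation genes rose by a median of 0.089 (adjusted p = 0.000794, adjusted p = 0.455 with an estimated correlation, 7.15e-05 to 0.455 over the alternatives). Atp5a1 was at 43.9 ± 1.5 CPM in IE and 37.2 ± 2.7 in SC. Gene length and fold change were correlated at Spearman -0.268 over 15557 genes, which are not independent replicates. With the gene length trend removed none of the 4 lists that fell passed (postsynaptic median -0.072, adjusted p = 0.0538), while oxidative phosphorylation genes did (median 0.055, adjusted p = 0.0257). CA1 markers had a median of -0.16 (adjusted p = 0.0755). The rapid immediate early genes did not pass (median -0.076, adjusted p = 0.0755, adjusted p = 0.585 with an estimated correlation, 6.85e-09 to 0.716 over the alternatives) but did without DG IE replicate 1 (-0.18) or DG SC replicate 1 (-0.14). Npas4 was at 2 ± 0.28 CPM in IE and 3.2 ± 0.64 in SC and Arc at 4.67 ± 0.84 CPM in IE and 6.81 ± 0.88 in SC. AP-1 subunits had a median of 0.10 (5 of 10 higher, adjusted p = 0.832). Jun was at 20.9 ± 4.1 CPM in IE and 14.8 ± 1.6 in SC. Of 19465 genes, 0 passed by edgeR and 996 had an unadjusted p under 0.05, where 973 would by chance. DESeq2 called 0 (803 unadjusted), and limma-voom 0. The 5 called lists had 0, 0, 0, 0 and 0 members past the threshold adjusted over the list alone by edgeR (3, 2, 2, 0 and 4 at an unadjusted p under 0.05). The postsynaptic median moved without SC replicate 1 (-0.071). The ionotropic call ended without IE replicate 3 (-0.13) and SC replicate 1 (-0.058), its median moving without IE replicates 1 (-0.20) and 2 (-0.17) and SC replicate 2 (-0.15). The channel call ended without IE replicate 3 (-0.084) and SC replicate 1 (-0.071), its median moving without IE replicate 2 (-0.13). The chromatin call ended without IE replicate 3 (-0.035) and SC replicate 1 (-0.041). The oxidative phosphorylation call ended without IE replicate 3 (0.071) and SC replicate 1 (0.028).

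Microglial, interneuron and oligodendrocyte genes rose in DG IE against SC, by medians of 0.34, 0.20 and 0.29 (13 of 14, 14 of 16 and 14 of 16 members higher). Adjusted p was 0.000794, 0.000794 and 1.49e-05, and 0.382, 0.382 and 0.382 with an estimated correlation. C1qa averaged 0.819 ± 0.29 CPM in IE and 0.43 ± 0.074 in SC, Sst 1.57 ± 0.43 CPM in IE and 0.822 ± 0.091 in SC and Opalin 1.37 ± 0.28 CPM in IE and 0.88 ± 0.19 in SC. Adjusted p of these lists ran 5.28e-05 to 0.382, 2.32e-05 to 0.382 and 3.09e-07 to 0.382 over the alternatives. Ribosomal protein genes rose in 78 of 82 cases by a median of 0.27 (adjusted p = 2.89e-19, adjusted p = 0.382 with an estimated correlation, 4.11e-27 to 0.905 over the alternatives), hosts and others alike (medians 0.296 and 0.246). Rps6 was at 4.44 ± 0.84 CPM in IE and 2.99 ± 0.51 in SC. Among single genes Terc, the telomerase RNA, averaged 2.31 ± 1.4 CPM in IE and 0.822 ± 0.18 in SC (log2 1.49, and 0.89 without IE replicate 1) and the kinesin gene Kif26a 1.78 ± 0.22 CPM in IE and 0.915 ± 0.15 in SC, with adjusted p = 0.93 for both. Ratios of Rnu5g, Rpl14-ps1, Hist2h2bb, Per2, Egfl6, Pid1 and Chrm3 were 3.49, 2.3, 1.56, 0.695, 0.599, 0.789 and 0.764, and Mir6236 averaged 0.528 ± 0.41 CPM in IE and 32.7 ± 56 in SC, a log2 fold change of -5.95 that was 0.41 without SC replicate 3. The 4 lists had 0, 1, 0 and 0 members past the threshold adjusted over the list alone by edgeR (4, 2, 5 and 19 at an unadjusted p under 0.05). The microglia call ended without SC replicate 1 (0.16), its median moving without IE replicate 3 (0.21). The interneuron median moved without SC replicate 2 (0.35). The ribosomal protein median moved without SC replicate 1 (0.17).

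**Figure D4:**
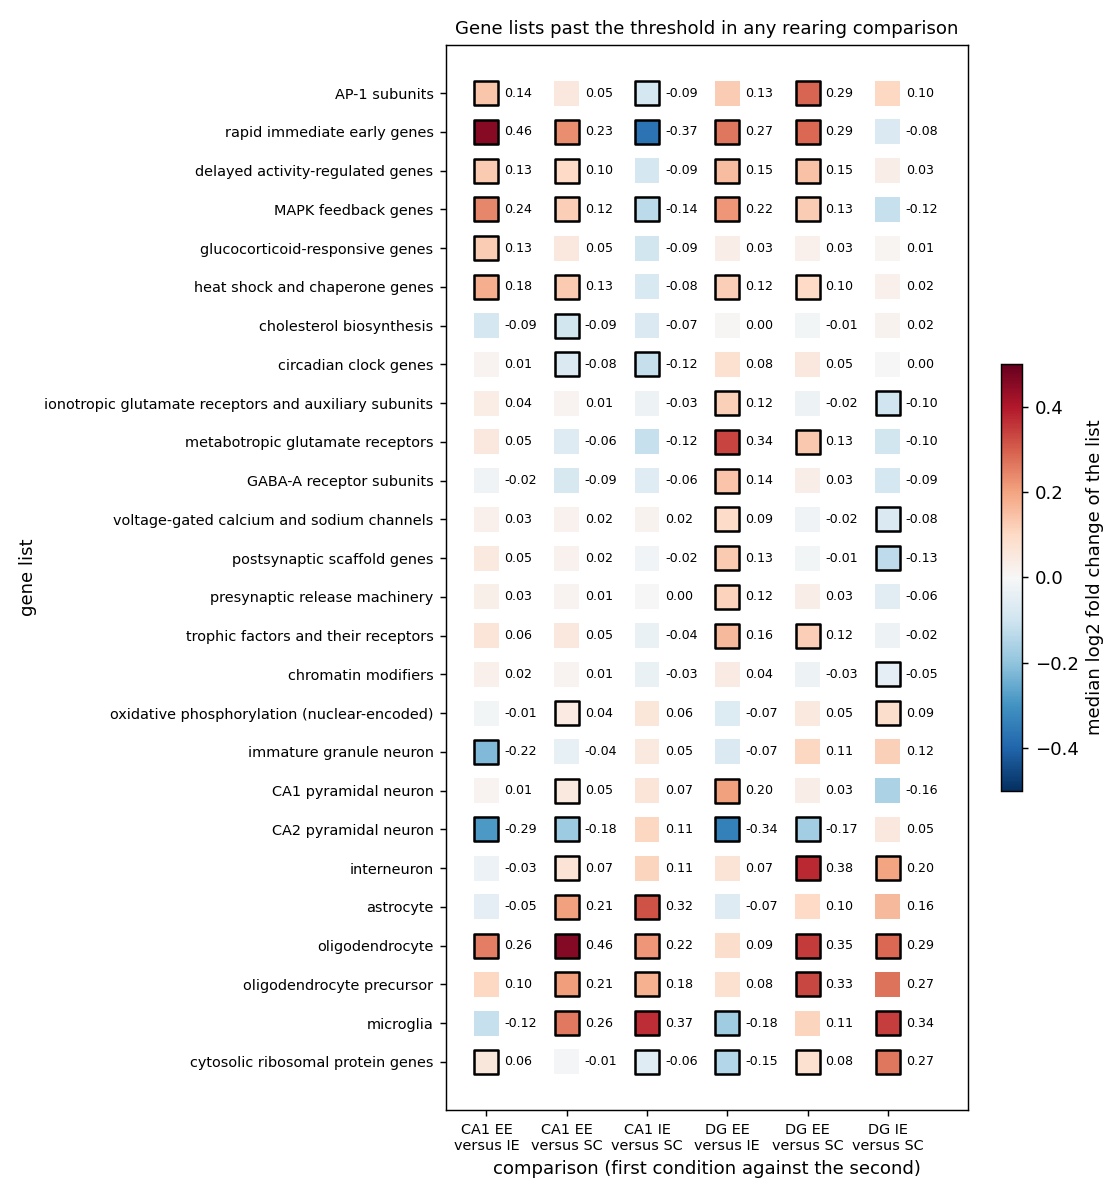
Median log2 fold change of the gene lists that passed the threshold in any rearing comparison. A black outline marks adjusted p under 0.05 with the preset correlation.

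Among immediate early genes Btg2 had the smallest p for a difference between the neuron types. Its EE against IE effect was lower in DG than in CA1 by a log2 difference of -0.96 ± 0.21 (SE, adjusted p = 1), beside -0.56 ± 0.21 for Jun and -0.64 ± 0.36 for Fosb. Other differences with small p were Ifi35 (-1.40 ± 0.36), Ccdc33 (-1.04 ± 0.30), Tdrd6 (-1.51 ± 0.38), Ldlrad1 (-1.65 ± 0.48), Zar1l (3.03 ± 0.65), Fam196b (0.95 ± 0.22), Gng4 (0.87 ± 0.22), Samd5 (0.71 ± 0.19) and Rasgef1b (0.67 ± 0.18). As lists, the EE against IE effects of immediate early genes (median -0.12, adjusted p = 0.0062, adjusted p = 0.582 with an estimated correlation, 2.34e-05 to 0.834 over the alternatives), AP-1 subunits (median -0.34, adjusted p = 0.0442, adjusted p = 0.545 with an estimated correlation, 0.0128 to 0.834 over the alternatives) and ribosomal protein genes (median -0.18, adjusted p = 3.12e-13, adjusted p = 0.439 with an estimated correlation, 1.29e-16 to 0.834 over the alternatives) were lower in DG. Metabotropic glutamate receptors had the larger effect in DG (median 0.30, adjusted p = 0.0223, adjusted p = 0.439 with an estimated correlation, 0.00368 to 0.834 over the alternatives), as with Grm8 (0.60 ± 0.39). The 4 lists had 1, 0, 0 and 0 members past the threshold adjusted over the list alone by edgeR (2, 1, 9 and 0 at an unadjusted p under 0.05). Of 20337 genes, 0 passed by edgeR and 490 had an unadjusted p under 0.05 where 1017 would by chance. DESeq2 and limma-voom called 0 (393 and 499 unadjusted). The immediate early difference ended without CA1 EE replicate 1 (-0.056), CA1 IE replicate 2 (-0.089) and DG EE replicate 3 (-0.10), its median moving without CA1 EE replicate 3 (-0.27), CA1 IE replicates 1 (-0.20) and 3 (-0.18) and DG EE replicates 1 (-0.23) and 2 (-0.18). The AP-1 difference ended without CA1 EE replicate 1 (-0.26), CA1 IE replicates 2 (-0.27) and 3 (-0.12), DG EE replicates 1 (-0.37) and 3 (-0.25) and DG IE replicates 1 (-0.23) and 2 (-0.36). The ribosomal protein median moved without DG EE replicate 3 (-0.12). The metabotropic difference ended without CA1 EE replicates 1 (0.23) and 2 (0.33), CA1 IE replicates 2 (0.37) and 3 (0.16), DG EE replicate 3 (0.15) and DG IE replicates 1 (0.25) and 2 (0.26).

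Btg2 and Rps3 had higher IE against SC effects in DG than in CA1, by log2 differences of 0.82 ± 0.21 (SE) and 1.12 ± 0.30 (adjusted p = 0.735 for both). Ribosomal protein genes as a list differed in the same way (median 0.28, adjusted p = 4.01e-26, adjusted p = 0.493 with an estimated correlation, 9.22e-33 to 0.942 over the alternatives), 11 members passing adjusted over the list alone, as did immediate early genes (median 0.16, adjusted p = 0.0108, adjusted p = 0.958 with an estimated correlation, 0.000243 to 0.967 over the alternatives), 1 member passing adjusted over the list alone, and AP-1 subunits (median 0.35, adjusted p = 0.0313, adjusted p = 0.927 with an estimated correlation, 0.00693 to 0.943 over the alternatives), with 0 past the threshold adjusted over the list alone and 1 at an unadjusted p under 0.05 by edgeR. The log2 difference of Jun was 0.51 ± 0.21. With the small RNA share as covariate the immediate early median was 0.002 (adjusted p = 0.967). For EE against SC ribosomal protein genes such as Rpl5 (0.82 ± 0.36) differed (median 0.092, adjusted p = 0.0261, adjusted p = 0.973 with an estimated correlation, 7.54e-07 to 0.999 over the alternatives), with 0 past the threshold adjusted over the list alone and 3 at an unadjusted p under 0.05 by edgeR. By edgeR 0 of 20337 genes passed for IE against SC (621 unadjusted) and 0 for EE against SC (740 unadjusted), where 1017 would by chance. DESeq2 called 8 (5 small RNA genes and 3 genes overlapping them) and 0, and limma-voom 0 and 0. Without DG SC replicate 2 edgeR called 40 for IE against SC. The ribosomal protein median moved without DG SC replicate 1 (0.18). The immediate early difference ended without CA1 IE replicate 2 (0.076), CA1 SC replicate 2 (0.11) and DG SC replicate 1 (0.14), its median moving without CA1 IE replicate 1 (0.25). The AP-1 difference ended without CA1 IE replicates 2 (0.37) and 3 (0.28), CA1 SC replicate 2 (0.20), DG IE replicate 1 (0.24) and DG SC replicates 1 (0.41) and 3 (0.31). The ribosomal protein difference for EE against SC ended without CA1 EE replicates 1 (0.062) and 3 (0.085), CA1 SC replicate 2 (0.02), DG EE replicates 1 (0.033) and 2 (0.064) and DG SC replicate 1 (-0.023), its median moving without CA1 SC replicate 1 (0.15), DG EE replicate 3 (0.15) and DG SC replicate 2 (0.15).

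Where SC lay between IE and EE was not computed, since 0 genes passed for EE against IE by edgeR in either neuron type (DESeq2 called 20 and 45). In CA1, Arc averaged 14.7 ± 3 CPM in IE, 22.6 ± 5.5 in SC and 31.7 ± 8.2 in EE, and in DG 4.67 ± 0.84, 6.81 ± 0.88 and 10.7 ± 2.4.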

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

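Among the tests in this part, those of gene length, GC content, CA1 genes in DG and small RNA genes were chosen only after the result was seen. The test with the non-neuronal marker score was written before, and leaving out single libraries was planned but not for this pattern. The rearing effects of 10 gene lists differed between the neuron types (DG minus CA1, with the median of each type in parentheses) in 15 list results, and 0 genes did by edgeR. For EE against IE, immediate early genes differed by a median of -0.12 (adjusted p = 0.0062, 0.582 with an estimated correlation, CA1 0.46, DG 0.27). AP-1 subunits differed by a median of -0.34 (adjusted p = 0.0442, 0.545 with an estimated correlation, CA1 0.14, DG 0.13). Metabotropic glutamate receptors differed by a median of 0.3 (adjusted p = 0.0223, 0.439 with an estimated correlation, CA1 0.054, DG 0.34), and Grm4 by 0.52 ± 0.31 (SE, range 0.25 to 0.70 with 1 library left out). GABA-A receptor subunits differed by a median of 0.16 (adjusted p = 0.016, 0.582 with an estimated correlation, CA1 -0.02, DG 0.14), and Gabra3 by 0.58 ± 0.35 (range 0.24 to 0.84). Cell proliferation genes differed by a median of -0.3 (adjusted p = 0.0426, 0.439 with an estimated correlation, CA1 0.15, DG -0.21), and Cenpf by -1.20 ± 0.44. CA1 markers differed by a median of 0.22 (adjusted p = 0.0426, 0.638 with an estimated correlation, CA1 0.012, DG 0.20). Oligodendrocyte genes differed by a median of -0.14 (adjusted p = 0.016, 0.439 with an estimated correlation, CA1 0.26, DG 0.087). Choroid plexus genes differed by a median of -0.25 (adjusted p = 0.0426, 0.439 with an estimated correlation, CA1 0.19, DG -0.32), and Ttr by -3.36 ± 1.10 (range -3.85 to -1.24). Ribosomal protein genes differed by a median of -0.18 (adjusted p = 3.12e-13, 0.439 with an estimated correlation, CA1 0.058, DG -0.15). With each of the 12 libraries left out in turn, the call ended (range of medians) in 11 (-0.32 to -0.10) fits for proliferation genes, 9 (0.12 to 0.31) for CA1 markers, 8 (-0.42 to -0.16) for choroid plexus genes, 5 (0.022 to 0.27) for GABA-A subunits and 4 (-0.35 to -0.082) for oligodendrocyte genes.

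For EE against SC, ribosomal protein genes differed by a median of 0.09 (adjusted p = 0.0261, adjusted p = 0.973 with an estimated correlation, CA1 -0.011, DG 0.081). For IE against SC, AP-1 subunits differed by a median of 0.35 (adjusted p = 0.0313, adjusted p = 0.927 with an estimated correlation, CA1 -0.089, DG 0.10). Immediate early genes of that contrast differed by a median of 0.16 (adjusted p = 0.0108, adjusted p = 0.958 with an estimated correlation, CA1 -0.37, DG -0.076), but by 0.002 with the small RNA share as covariate (adjusted p = 0.967). Calcium and sodium channels differed by a median of -0.14 (adjusted p = 0.0333, adjusted p = 0.927 with an estimated correlation, CA1 0.016, DG -0.078), and Cacnb2 by -0.28 ± 0.16 (range -0.38 to -0.18). CA1 markers of that contrast differed by a median of -0.21 (adjusted p = 0.0114, adjusted p = 0.927 with an estimated correlation, CA1 0.066, DG -0.16), and Wfs1 by -0.49 ± 0.24 (range -0.69 to -0.26). Ribosomal protein genes of that contrast differed by a median of 0.28 (adjusted p = 4.01e-26, adjusted p = 0.493 with an estimated correlation, CA1 -0.06, DG 0.27). With each of the 12 libraries left out in turn, the call ended in 6 (-0.30 to -0.087) fits for channels and 4 (-0.43 to -0.12) for CA1 markers.

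As a list with Fos, Arc and Egr1, rapid immediate early genes were higher in EE than in IE in both neuron types (medians 0.46 and 0.27, 30 of 30 and 22 of 28 members). Neither list passed with an estimated correlation (adjusted p = 0.186 and 0.206). With the length trend or the transcript GC trend removed the lowest of the 4 list medians was 0.294, so neither is the whole cause. With the score of non-neuronal markers as covariate the CA1 median was 0.473 (adjusted p = 4.62e-29, and 0.157 with an estimated correlation). Non-neuronal nuclei are thus not the whole cause there. In DG the median was 0.166 ± 0.069 (SE over members) instead of 0.27, so a part from such nuclei cannot be told apart from activity. Without any 1 library the CA1 median was at least 0.324. The DG median fell to 0.144 without EE replicate 1, which may carry part of it. More recent neuronal activity in enriched mice could be a cause, but it was not measured, and nuclei of other neuron types and a difference by chance (1 of 10 splits, the real one, as large in CA1 and 3 of 10 in DG) stay open.

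The 7 synaptic, channel and trophic lists, with Grm4, Nrg1 and Lrrtm3, were higher in DG EE than in DG IE as lists, not in every member. None passed with an estimated correlation. At the preset one, 1 list passed with the length trend removed and 6 with the GC trend removed. A length-related difference between libraries may thus carry most of these calls and GC content does not. List members had a median length of 108 kb against 19.6 kb over all tested genes. Members at least 1.5 times as high in CA1 as DG had a median of 0.265 ± 0.037 and the others 0.11 ± 0.011 (SE over members). More CA1 nuclei in DG EE libraries may add to the effect, to an untested extent.

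Rps2, Rps3, Rpl10, Rpl23 and other ribosomal protein genes with small nucleolar RNAs in their introns were lower in CA1 IE than in CA1 SC. The ribosomal protein list did not pass with an estimated correlation. Without small RNA genes and genes overlapping them its median was 0.044 instead of -0.06, as counts of the small RNAs inside these genes could give. With the gene length trend removed the median was -0.041, so length is not the cause.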

How the results depend on the processing

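Among the tests in this part, the fits without small RNA genes, with a trend removed and with the small RNA share and the matchings of numbers were chosen only after the result was seen. Gene counts of 0 by edgeR rose without the filter on low counts to 22 (18 higher, 4 lower), 3 (1, 2) and 121 (1, 120) in CA1 EE against IE, EE against SC and IE against SC, 320 (263, 57), 297 (264, 33) and 87 (71, 16) in DG, and 45, 178 and 223 for the differences, where the prior degrees of freedom went from 5.2 to 36.7 in CA1, from 6.64 to infinite in DG and from 5.75 to 143 over both. With DESeq2 they were 20, 2, 69, 45 and 23, and 8 for the IE against SC difference, and the cause was not tested. The replicate block gave 1 gene (Arhgef37) in CA1 EE against IE and 2 in CA1 IE against SC, 11835 instead of 10174 in CA1 against DG, and 0 elsewhere. Libraries of one number were correlated over 0.1 in 7 of 9 pairs of neuron types (mean 0.383, as large in 5 of 216 matchings of the numbers) and in 10 of 18 pairs of conditions (mean 0.233 in CA1, 3 of 36 matchings, and 0.104 in DG, 7 of 36), so CA1 and DG libraries of one number may share mice or handling, which could add to the correlation of their effects. The fit on all 18 libraries gave 1 (Pla2g7) in CA1 EE against SC and 3 (Etl4, Pid1, Lhfp) in DG EE against IE. Leaving out 1 library gave 0 to 1 in DG EE against IE, 0 to 2 in DG EE against SC, 0 to 40 for the IE against SC difference, 9632 to 10545 for CA1 against DG and 0 to 0 elsewhere. The correlation of effects was 0.385 at 10 CPM or more, and 0.173 to 0.372 with 1 library left out (0.173, 0.225 and 0.372 without CA1 IE replicates 1, 2 and 3, 0.232 without DG EE replicate 1, 0.217 without DG IE replicate 2). Ribosomal protein medians turned to -0.045 (CA1 EE against IE) and 0.044 (CA1 IE against SC) without small RNA genes, and in DG EE against SC to -0.037 with the small RNA share and in test direction at 0.011 without DG SC replicate 1 (0.011 to 0.18 over libraries left out). The immediate early difference for IE against SC was 0.002 with that share. Of 90 rearing list results, fry ended 84 calls, an estimated correlation 83, the small RNA share 32 and length removal 19.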

Other observations

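Among the tests in this part, those of the MAPK list without shared members, genes of CA1 or DG type, the GC trend and the permutation that keeps CA1 and DG libraries of one number together were chosen only after the result was seen. The score of the MAPK feedback list, with Dusp5 and Etv5, rose in order from IE over SC to EE over the libraries of both neuron types (steps of 0.151 in CA1 and 0.125 in DG, permutation p = 1e-05, adjusted p = 0.00035), and without the 3 members on the immediate early list at permutation p = 0.00011. These permutations move CA1 and DG libraries apart, but those of one number may share mice. Moved together, the MAPK list had adjusted p = 0.0417 (permutation p = 0.00119, the smallest that 1680 arrangements can give) and permutation p = 0.00833 without the shared members. Immediate early genes had steps of 0.292 and 0.204 (adjusted p = 0.00105 moved apart and 0.0833 together) and CA2 markers steps of -0.123 and -0.139 (0.0422 and 0.258), so their order depends on whether the libraries are pairs. AP-1 subunits (0.0656 and 0.286) and oligodendrocyte genes (0.589 and 0.826) did not pass in either.

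Several lists passed in no rearing comparison, with medians over the 6 comparisons of -0.035 to 0.011 for potassium channels, -0.04 to 0.099 for extracellular matrix genes, -0.18 to 0.21 for mature granule neuron markers, -0.11 to 0.037 for CA3 markers, -0.12 to 0.056 for mossy cell markers, 0.005 to 0.24 for endothelial markers, -0.20 to 0.04 for thalamic markers, -0.32 to 0.25 for choroid plexus markers and -0.21 to 0.15 for proliferation genes. Lists with fewer than 3 tested members were not tested: for EE against IE the blood genes Hbb-bs (0.85 ± 0.42 in CA1 and -0.14 ± 0.27 in DG, ± SE) and Alas2 (-0.14 ± 0.55 in CA1 and 0.21 ± 0.41 in DG), Xist (-0.12 ± 0.13 in CA1 and -0.16 ± 0.12 in DG) and Tsix (-0.052 ± 0.23 in CA1 and -0.003 ± 0.18 in DG), and mitochondrially encoded genes, of which 0 had counts.

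Genes of CA1 type scored 0.361, -0.187 and 0.473 in the 3 DG EE libraries, -0.331, -0.048 and 0.166 in DG SC and -0.223, -0.232 and 0.021 in DG IE (64 genes), and 37 genes 4 to 8 times higher in CA1 than in DG had a median of 0.379 in DG EE against IE.

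With labels exchanged, splits of 3 against 3 libraries are too few (10) for a share under 0.05. The real edgeR count of 0 was matched by every split. Highest others were 2000, 0 and 462 for CA1 EE against IE, EE against SC and IE against SC, and 1046, 0 and 33 in DG. DESeq2 reached its real counts in 2, 3 and 2 of 10 splits, the real one included, in CA1 (highest others 3005, 28 and 1412). In DG it did in 2, 1 and 10 (2211, 15 and 139). For differences between neuron types highest others of 40 drawn splits were 2868, 0 and 295 (real 0), and for CA1 against DG 3723 (real 10174). For EE against IE immediate early medians were 0.456 in CA1 (highest other 0.384, 1 of 10) and 0.268 in DG (0.364, 3 of 10). The correlation of effects was 0.298 (0.598, 20 of 100). In both neuron types the split with most calls put EE replicate 1 with IE replicates 1 and 2, and libraries differed in a GC content trend (Spearman -0.66 to 0.55 over 13497 genes, not independent replicates), so the largest structure among libraries may be technical.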
